A study of Mus musculus with 12 samples.

How the data were processed

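The series holds 12 one-colour microarrays of mouse B cells. Per the labels, splenic B cells of female Balb/c mice, control or made allergic to house dust mite (HDM), were cultured with a CD40 agonist and received LPS near the end. They were stained with an IL-10 secretion assay and sorted by flow cytometry into IL-10+ and IL-10- cells. There were 4 groups of 3 arrays: IL-10+ control, IL-10- control, IL-10+ HDM and IL-10- HDM. The labels do not say whether the 3 samples of a group came from separate mice or cultures, so the p-values measure a spread between samples that may in part be technical.

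Per the labels, the authors amplified cDNA from bead-isolated mRNA by PCR (SuperAmp, a method for few cells) and labelled it with Cy3. Per the file headers, the arrays were of Agilent design 028005 with annotation on genome build mm9, and were read with Agilent Feature Extraction 10.7.3.1. The deposited scanner files give intensity values in the processed signal column: background-subtracted, spatially and multiplicatively detrended, and not normalised between arrays. They also give the intensity of the mean spot signal and of the local background as scanned, and per-spot flags, which are other values and not intensities per the file headers. The deposited value table holds a ratio: the processed signal of each spot divided by that array's median over all gene spots. This was found by recomputation from the scanner files, with a largest deviation of 0.00077%, and every column has a median of 1.

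Each array had 59305 gene spots for 55681 probes. No spot was saturated. The header's median coefficient of variation of replicate spots was 5.42% to 8.39%. As arrays give no counts, the number of arrays limits the precision. Probes were kept when they were well above background by the scanner's flag on at least 3 of the 12 arrays, which 37727 were. Another 79 probes were left out because every spot of the probe was marked as an outlier on some array. The log2 processed signal minus the array's 75th percentile was used, with 1 probe per gene, the one with the highest mean over the 12 arrays. This left 24944 genes, of which 7360 had 2 or more eligible probes. Of them, 10650 carry clone, accession or chromosome-position names, and 129 are immunoglobulin segments.

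Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 mean for each of the 4 groups, so that all 12 arrays gave the estimate of the spread. The model had 8 residual degrees of freedom, 2.12 prior degrees of freedom and a prior SD of 0.648. There were 6 comparisons: IL-10+ against IL-10- cells in control mice, in HDM mice and averaged over both, HDM against control mice in IL-10+ and in IL-10- cells, and the difference of the IL-10 contrast between HDM and control mice. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Counts at an unadjusted p under 0.05 are given beside the calls. Without any change, a share of 0.05 of the tested genes is expected there, so such a count alone shows no change. For Il10 and Cd9, an exact two-sided permutation test within control and HDM mice was added.

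The genes named in the text followed a rule. It takes Il10, the sort target, and Cd9, named in the series title, in every comparison. For each comparison it takes up to 12 higher and 12 lower called genes with the largest fold change, no overlap between the arrays of the compared groups, a signal well above background on every array of the higher group, and a gene symbol. For the interaction, the rule sets no condition on overlap. Where no gene passes, it takes the 5 with the smallest p, without these conditions. It also takes up to 4 members of each gene list that was called or that marks another cell type. A pair of 3-array groups fails to overlap by chance for 10% of genes. Other named genes were chosen after their values were seen, and this is said where they appear.

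The 34 gene lists held 712 symbols, 9 without a probe. They covered B cell identity, regulatory B cell markers, IL-10-linked transcription factors, plasmablasts, marginal zone, B-1, follicular and germinal centre B cells, cytokines and chemokines, NF-kB and LPS response, immediate early genes, IL-4 and STAT6 response, type I interferon response, MHC class II, costimulation, unfolded protein response, protein translocation, DNA replication, mitosis, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, ribosomal proteins, heat shock and p53 targets. Lists of markers of other cell types covered T cells, NK cells, monocytes, dendritic cells, neutrophils, erythroid cells, platelets and stroma. A mast cell and basophil list had fewer than 5 measured members and was not tested. The other 33 were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists of a comparison, beside camera with an estimated correlation and fry. In the order control mice, HDM mice and averaged for the sort, IL-10+ and IL-10- cells for HDM against control mice, and the interaction, camera called 5, 12, 10, 4, 4 and 8 lists and fry 3, 11, 8, 0, 1 and 0. Lists share genes: Ctla4 and Tigit stand in several, and Cd9 stands in the regulatory, marginal zone and platelet lists. Many marker lists contain genes that B cells also express. The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

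A gene that was not well above background on any array of the dimmer side was given a fold as a lower bound. The bound holds for the probe used, and other probes of the gene can lie under it. The bound is the mean of the bright side minus the mean of the dim side on the log2 scale. Each dim array was set to the faintest signal flagged well above background on it, or to its own value where that was higher.

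The arrays lay on 2 slides. Slide 1 held all 6 IL-10+ arrays and IL-10- control arrays 1 and 2, and slide 2 held IL-10- control array 3 and all 3 IL-10- HDM arrays. Every comparison was therefore also fitted with slide as a block and, where 1 slide held both groups, within that slide. Other alternatives were quantile normalisation, normexp background correction (offset 50) with either scaling, centring on the tested-gene median, no filter on dim probes, filters at 6 or all 12 arrays, the mean of a gene's probes, only the groups compared, eBayes with trend and robust options, array weights, slide as a random block, the replicate number as a block, the deposited ratio table, a fold of at least 2, and leaving out each array in turn. Leaving out IL-10- HDM array 3 and IL-10+ control array 2 together was chosen after seeing the data. Il10 has 1 probe, so no other Il10 probe could be compared.

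Gene symbols and gene order came from the reference gene table on build GRCm38, matched by RefSeq accession, and probe positions from the scanner files on mm9. Probe sequences were not realigned. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and the R package data.table (version 1.17.8) read and wrote tables. The workflow was tested on simulated data built from each gene's mean and residual spread. With 3 arrays against 3 it called 34% of 50 genes changed by 2 on the log2 scale and 56% of 50 changed by 4, and 2 of 24719 unchanged genes. In the averaged comparison it called 50% and 76%, and 6 of 24719 unchanged genes. The simulated values varied independently between genes and alike on all arrays, without a slide effect, a detection floor or an outlying array. These shares therefore do not cover errors from such sources in the real data. The value of 1 member of a gene list is not reported here.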

Results

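The arrays compared B cells that secreted IL-10 (IL-10+) with B cells that did not (IL-10-), each from control mice and from mice with house dust mite (HDM) allergy, with 3 arrays per group. Between 47.7% (IL-10- HDM array 3) and 62.4% (IL-10- control array 3) of spots were well above background. Signals are given as log2 of the processed signal over the array's 75th percentile, and differences as log2 fold changes with their standard error (SE) from limma. All groups had n = 3, so the averaged comparison set 6 IL-10+ arrays against 6 IL-10- arrays. Genes named by rule below had no overlap between the compared groups, apart from Il10, Cd9 and members of gene lists. This was also not required of the interaction genes or of genes named for the smallest p. IL-10- HDM array 3 stood apart from the rest, with a mean correlation of 0.775 across genes with the other 11 arrays, against 0.867 to 0.901 for the others. Among the tested genes, 73.0% were well above background on that array and 78.6% on IL-10+ control array 2, against up to 90.9% on IL-10- control array 3.

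**Figure D1:**
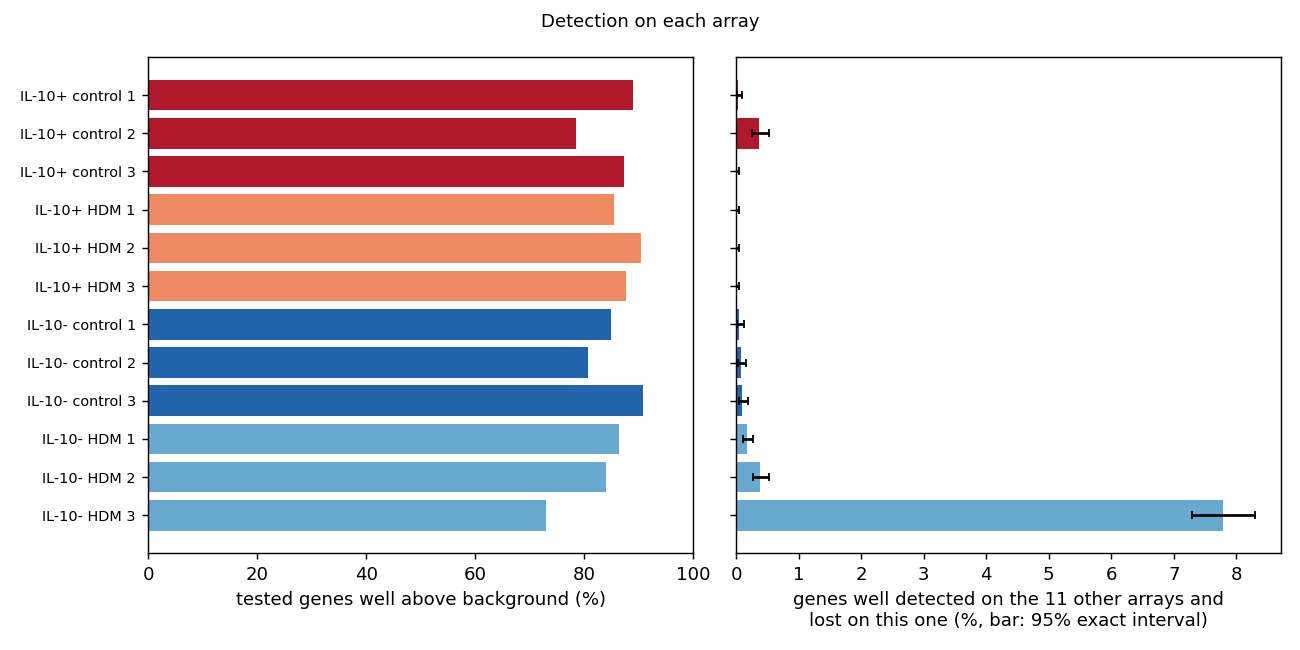
Percent of the tested genes well above background on each of the 12 arrays, and percent lost on each array of the genes that were well above background on the other 11 arrays and at least 4 log2 units above the array's floor. IL-10- HDM array 3 had the lowest share detected (73.0%) and the highest share lost (7.78%).

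The transcript of the sorted cytokine followed the sort on every array. Il10 was measured by 1 probe printed in 10 spots (mm9, chromosome 1, 132920943 to 132921002). Its level was 7.15 ± 0.37 (SD, n = 3) in IL-10+ and 0.59 ± 0.59 (SD, n = 3) in IL-10- cells of control mice. In HDM mice it was 6.76 ± 0.29 (SD, n = 3) and -1.85 ± 3.1 (SD, n = 3), the wide spread coming from IL-10- HDM array 3 at -5.43, where the probe was not well above background. Averaged over both mice, Il10 was 192-fold higher in IL-10+ cells (log2 fold change 7.59, SE 0.84, adjusted p = 0.0080), or 6.69 on the log2 scale without IL-10- HDM array 3. Cd9, the tetraspanin that the series title names, was measured by 1 spot (mm9, chromosome 6, 125410387 to 125410446). Its level was 1.62 ± 0.96 (SD, n = 3) in IL-10+ and -3.18 ± 1.27 (SD, n = 3) in IL-10- cells of control mice, and 1.05 ± 0.38 (SD, n = 3) and -3.19 ± 1.31 (SD, n = 3) in HDM mice. In each IL-10- group, 2 of the 3 arrays had a Cd9 signal well above background. Averaged over both mice, Cd9 was 22.9-fold higher in IL-10+ cells (log2 fold change 4.52, SE 0.56, adjusted p = 0.013). For both genes the exact permutation test within control and HDM mice gave p = 0.005, the smallest that its 400 arrangements allow. In a fit with slide as a block, the averaged log2 fold change was 6.96 (SE 1.5) for Il10 and 4.73 (SE 1.03) for Cd9, with an adjusted p of 0.27 for each. Within slide 1, control mice alone gave 6.25 for Il10 and 4.90 for Cd9.

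**Figure D2:**
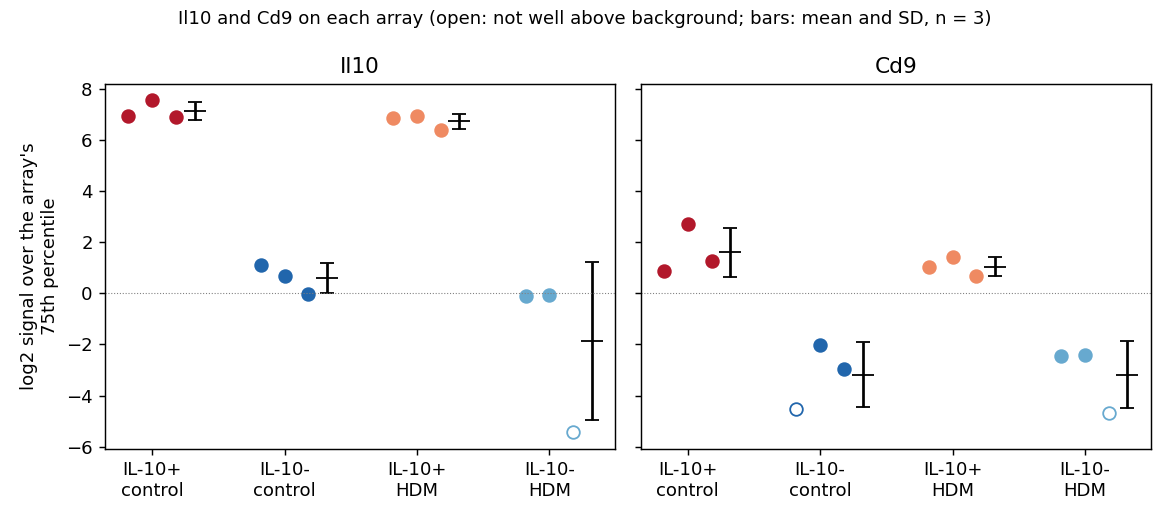
Level of Il10 and Cd9 on each array (log2 over the array's 75th percentile) by group, with the mean and SD of 3 arrays; open points were not well above background. Il10 lay at 7.15 and 6.76 on average in the IL-10+ groups against 0.59 and -1.85 in the IL-10- groups.

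Averaged over control and HDM mice, the genes called higher in IL-10+ cells included the antibody joining chain, a cytokine, a chemokine and an inhibitory receptor. Jchain, which joins IgM and IgA into polymers in antibody-secreting cells, was higher by 6.84 on the log2 scale (SE 0.62, adjusted p = 0.0045), with 2 of 6 IL-10- arrays well above background. Il19, a cytokine of the IL-10 family, was not well above background on any IL-10- array and at least 30.1-fold higher (adjusted p = 0.010). Ctla4, an inhibitory receptor best known from T cells, was higher by 5.97 (SE 0.81, adjusted p = 0.017), with 3 of 6 IL-10- arrays well above background. Ccl22, a chemokine that attracts CCR4+ T cells, was 19.6-fold higher (log2 fold change 4.29, SE 0.41, adjusted p = 0.0046) and was well above background on all 12 arrays. Nt5e, which encodes the adenosine-producing enzyme CD73, was at least 9.10-fold higher (adjusted p = 0.012), and Csf2rb2, a subunit of the mouse IL-3 receptor, at least 8.45-fold higher (adjusted p = 0.0045). The costimulatory ligand Cd70 was higher by 4.85, the surface protein Ly6c1 by 4.67 and the glutaredoxin Glrx by 4.58 on the log2 scale, with 3, 2 and 1 of 6 IL-10- arrays well above background, and the biotin ligase Hlcs was at least 9.84-fold higher. The sizes for Jchain, Ctla4, Cd70, Ly6c1 and Glrx thus rest in part on signals not well above background. The lower genes changed less: Dnajb9, an endoplasmic reticulum chaperone, fell by 1.66 on the log2 scale (SE 0.24, adjusted p = 0.026). Blnk, an adaptor of the B cell receptor, fell by 1.56 (SE 0.24, adjusted p = 0.034) and the F-box protein Fbxo22 by 1.47 (SE 0.23, adjusted p = 0.036). For several of these genes another probe gave a smaller log2 value of the same sign: 2.68 for Il19, 1.75 for Hlcs, 2.42 for Ly6c1, 2.83 for Csf2rb2 and -0.89 for Dnajb9. For Il19, Hlcs and Csf2rb2 these values lie under the bounds given above, so those bounds hold only for the probe used.

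In total 67 of 24944 genes were called in the averaged comparison, 61 higher and 6 lower in IL-10+ cells, and 64 of them had the same sign in control and in HDM mice. As they were called on the mean of these contrasts, such agreement is in part built in. Over all 24944 genes, the contrasts in control and in HDM mice correlated at 0.154. With a block for slide, 0 genes were called by limma, with 1757 at an unadjusted p under 0.05. All 67 kept their sign in that fit and 66 had an unadjusted p under 0.05, while their median log2 fold change, taken in the direction of the call, went from 3.27 to 3.22 and their median SE from 0.438 to 0.732. Only the IL-10- control group lay on both slides, so its 3 arrays alone set the slide term. In that fit the log2 fold changes were 7.04 (SE 1.13) for Jchain, 5.41 for Il19, 5.56 for Ctla4, 3.73 for Ccl22, 3.49 for Csf2rb2, 4.61 for Hlcs, 4.60 for Nt5e, 6.63 for Ly6c1, 6.96 (SE 0.92) for Glrx, -2.11 for Dnajb9, -1.75 for Blnk and -1.16 for Fbxo22. Cd70 fell from 4.85 (SE 0.81) to 1.88 (SE 0.84), so its fold depended on the slide term. With the replicate number as a block 0 genes were called by limma and 2606 had an unadjusted p under 0.05, all 67 among them. Their folds were the same and their median SE was 0.401, with 4 instead of 8 residual degrees of freedom. Within slide 1, control mice alone gave the same sign for 65 of the 67, with 6.56 for Jchain, 6.40 for Il19, 5.71 for Ctla4 and 3.26 for Ccl22. The arrays of these refits had also served to call the 67 genes, so the kept signs are no independent support. The count was 31 without IL-10+ control array 3, 33 without IL-10+ HDM array 2, 137 without IL-10- HDM array 1 and above 100 without IL-10- HDM array 2. Il10, Cd9, Jchain, Il19, Nt5e, Csf2rb2 and Ccl22 were called whichever single array was left out. Ctla4 was not called without IL-10+ control array 3 (adjusted p = 0.0585) or IL-10+ HDM array 2 (0.0609), nor Hlcs without IL-10+ control array 3 (0.0550). Cd70, Ly6c1, Glrx, Dnajb9, Blnk and Fbxo22 kept their call in 3, 4, 2, 4, 1 and 2 of the 12 omissions, with an adjusted p of at most 0.124.

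**Figure D3:**
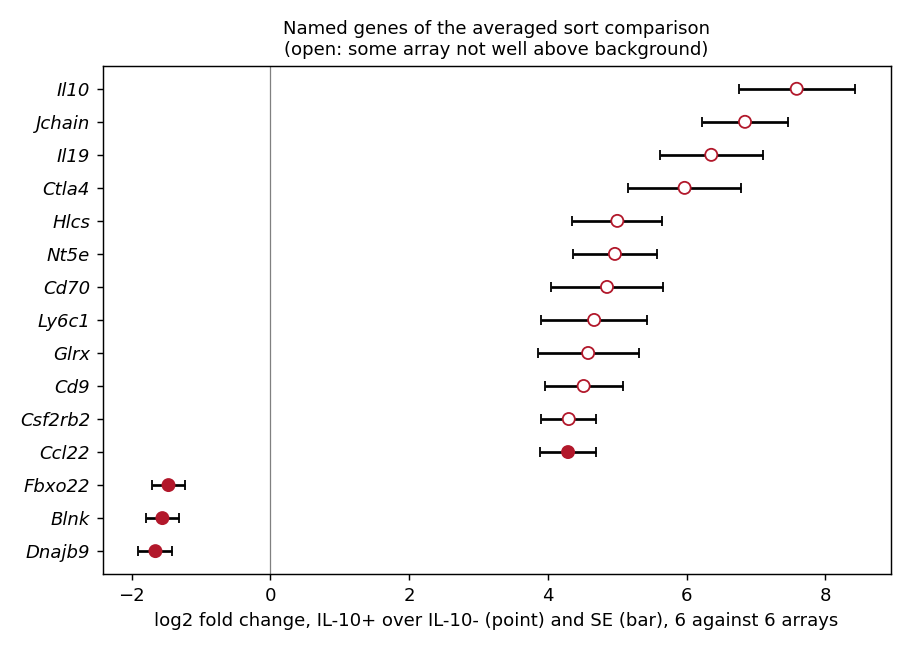
Log2 fold change between IL-10+ and IL-10- B cells averaged over control and HDM mice for the 15 genes named by rule, with bars of 1 SE; open points rest on some arrays not well above background. The 12 higher genes lie between 4.29 (Ccl22) and 7.59 (Il10), and the 3 lower genes between -1.66 (Dnajb9) and -1.47 (Fbxo22).

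Markers of regulatory B cells, plasmablasts and B-1 cells were higher in IL-10+ cells in the averaged comparison. Of the 21 measured regulatory B cell markers, 16 were positive, with a median log2 fold change of 0.40 (camera adjusted p = 1.00e-04, adjusted p = 0.035 with an estimated correlation). Of them 5 passed when adjusted over the list alone and 3 over all genes: Nt5e, Cd9 and Ctla4. Tigit, another inhibitory receptor, rose by 5.01 (SE 1.01, adjusted p = 0.094 over all genes). The plasmablast list (13 of 19 positive, median 0.38) had an adjusted p = 4.93e-04, and adjusted p = 0.035 with an estimated correlation; 5 members passed adjusted over the list alone, and Jchain and Ly6c1 over all genes. The B-1 list (10 of 14 positive, median 0.50) had an adjusted p = 5.29e-04, and adjusted p = 0.035 with an estimated correlation. Adjusted over the list alone, 6 B-1 members were higher and 1 was lower, and Ptpn22 (at least 4.80-fold, adjusted p = 0.013) and Ctla4 passed over all genes. Among them Bhlhe41, a repressor that maintains B-1 cells, rose by 4.92 (SE 0.92) and its paralog Bhlhe40 fell by 1.42 (SE 0.39). The costimulation list (14 of 23 positive, median 0.43, adjusted p = 0.018; adjusted p = 0.139 with an estimated correlation) shares 6 members with the regulatory list, and 6 of its members were higher and 1 lower adjusted over the list alone, with Ctla4 and Cd70 called over all genes. The type I interferon list (19 of 25 positive, median 0.42) had an adjusted p = 0.040, and adjusted p = 0.406 with an estimated correlation; 2 members passed adjusted over the list alone and 0 over all genes.

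Lower in IL-10+ cells in the averaged comparison were genes of sterol synthesis, early activation and translation. The 24 cholesterol biosynthesis genes had a median of -0.72 with 20 negative (adjusted p = 1.82e-09; adjusted p = 0.064 with an estimated correlation), among them Sqle at -1.42 (SE 0.36) and Hmgcs1 at -1.16 (SE 0.32). Of the 21 immediate early genes 18 were negative, with a median of -0.74 (adjusted p = 2.89e-04; adjusted p = 0.250 with an estimated correlation), including the nuclear receptor Nr4a1 at -1.61 (SE 0.32). Ribosomal proteins (33 of 37 negative, median -0.32, adjusted p = 1.83e-05), heat shock genes (12 of 16 negative, median -0.58, adjusted p = 0.00116) and DNA replication genes (19 of 28 negative, median -0.48, adjusted p = 0.018) were also lower. With an estimated correlation these 3 gave adjusted p = 0.627, adjusted p = 0.366 and adjusted p = 0.366. Adjusted over the list alone, 4 cholesterol and 3 immediate early genes were lower; no member of these 5 lists was called over all genes. Blocking on slide, camera still called the regulatory (adjusted p = 0.0079), plasmablast (0.0037) and B-1 (0.0041) lists and all 5 lower lists, but not the costimulation and interferon lists. Within slide 1, control mice alone gave a lower cholesterol list (median -0.50, camera adjusted p = 2.1e-04). The immediate early (-0.35, 0.438), ribosomal (-1.1e-04, 0.908), heat shock (-0.18, 0.598) and DNA replication (-0.47, 0.111) lists were not called there. Apart from the cholesterol list, these lower shifts were thus not shown outside HDM mice, where sort and slide coincide. The regulatory, plasmablast, B-1, cholesterol, immediate early, ribosomal and heat shock lists were called whichever array was left out. Without IL-10- HDM array 3 the immediate early, ribosomal and heat shock medians were -0.48, -0.19 and -0.38, and without IL-10+ HDM array 1 the plasmablast median was 0.68. The costimulation list was not called without IL-10+ control array 2 (adjusted p = 0.0789), IL-10- control array 1 (0.050) or IL-10- HDM array 1 (0.0789), and the DNA replication list not without IL-10- control array 2 (0.282) or IL-10- HDM array 3 (0.0847). The interferon list kept its call in 4 of the 12 omissions. The other 8 gave an adjusted p of 0.0504 (without IL-10- control array 1) to 0.226 (without IL-10- HDM array 2). Its median was 0.16 without IL-10- HDM array 2 and 0.17 without IL-10- HDM array 1.

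**Figure D4:**
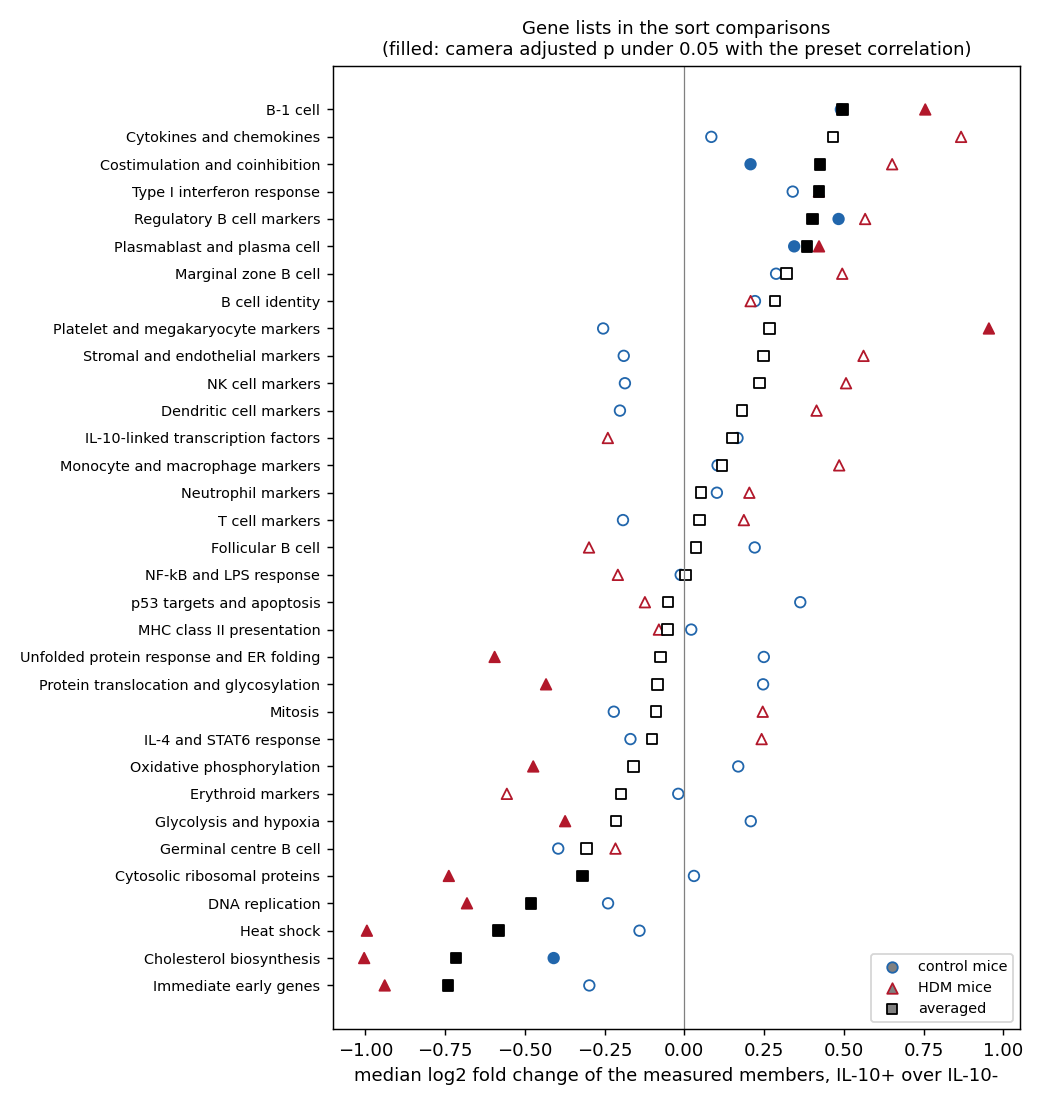
Median log2 fold change of each gene list between IL-10+ and IL-10- B cells in control mice (circles), HDM mice (triangles) and averaged (squares); filled symbols had a camera adjusted p under 0.05. The regulatory list lies at 0.40 and the cholesterol list at -0.72 in the averaged comparison.

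The other lists were not called in the averaged comparison. Their medians were 0.28 for B cell identity (adjusted p = 0.625), 0.32 for marginal zone cells (0.119), 0.04 for follicular cells (0.931), 0.47 for cytokines and chemokines (0.122), -0.16 for oxidative phosphorylation (0.122), -0.21 for glycolysis (0.426) and -0.09 for mitosis (0.517). Among markers of other cell types, medians were 0.05 for T cells (0.848), 0.24 for NK cells (0.545), 0.12 for monocytes (0.225), 0.18 for dendritic cells (0.603), 0.05 for neutrophils (0.803), -0.20 for erythroid cells (0.517), 0.27 for platelets (0.225) and 0.25 for stroma (0.625). In 9 lists the median, the mean and the direction of the test differed in sign, none of them called. These were the IL-10-linked transcription factors (median 0.15, test lower, adjusted p = 0.517), germinal centre (-0.31, mean 0.05), NF-kB (0.00, test lower, adjusted p = 0.545), IL-4 and STAT6 (-0.10, mean 0.29), MHC class II (-0.05, mean 0.02), unfolded protein response (-0.07, mean 0.03, adjusted p = 0.311), protein translocation (-0.08, mean 0.10), p53 (-0.05, mean 0.34) and erythroid (mean 0.06) lists. None of these medians was tested for a difference from 0 by itself. In the fit with slide as a block, camera also called the platelet list higher (median 0.70, adjusted p = 0.0463) and the unfolded protein response (-0.45, 0.00369), protein translocation (-0.39, 0.00788) and oxidative phosphorylation (-0.54, 0.00369) lists lower.

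In control mice alone, IL-10+ cells carried more Lgr4, a receptor for R-spondins, by at least 2.97-fold (log2 fold change 3.67, SE 0.33, adjusted p = 0.0062). Selplg, which encodes the selectin ligand PSGL-1, was 9.74-fold higher (log2 fold change 3.28, SE 0.39, adjusted p = 0.042), and its other probe gave 2.72. The cytoskeletal protein gene Epb41l1 was at least 1.72-fold higher (adjusted p = 0.034). Il10 was 94.6-fold higher (log2 fold change 6.56, SE 1.18) and Cd9 27.8-fold higher (log2 fold change 4.80, SE 0.80), but neither passed over all genes (adjusted p = 0.22 and 0.19). Without IL-10- HDM array 3, whose Il10 value lay far from its group, Il10 had an adjusted p = 4.66e-04 at the same fold. In all 4 genes were called, all higher. There were 1013 genes at an unadjusted p under 0.05, fewer than the share of 0.05 expected without any change. The count of called genes was 1 without IL-10+ control array 3 and 7 without IL-10- HDM array 3. Lgr4 was not called without IL-10+ control array 3 (adjusted p = 0.0535); Selplg kept its call in 3 and Epb41l1 in 4 of the 12 omissions, with an adjusted p up to 0.214. The fit with slide as a block called 4 genes, 2 of them shared, and Lgr4 was at 3.48 (adjusted p = 0.027) and Selplg at 3.40 (adjusted p = 0.12). Blocking on the replicate number, limma called 0 genes, with 1182 at an unadjusted p under 0.05. Within slide 1 alone 3 genes were called, Il10 (6.25) among them, while Lgr4 (3.48), Selplg (3.40) and Epb41l1 (2.85) were not called there.

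In control mice 5 of the 10 lists of the average were called, and the immediate early, ribosomal, heat shock, DNA replication and interferon lists were not. The regulatory list (17 of 21 positive, median 0.48, adjusted p = 4.44e-07; adjusted p = 0.0083 with an estimated correlation) and the plasmablast list (16 of 19, 0.34, adjusted p = 1.84e-04; adjusted p = 0.020 with an estimated correlation) were higher. So were the B-1 list (10 of 14, 0.49, adjusted p = 1.84e-04; adjusted p = 0.020 with an estimated correlation) and the costimulation list (16 of 23, 0.21, adjusted p = 0.00125; adjusted p = 0.047 with an estimated correlation). Adjusted over the list alone 6, 3, 4 and 3 members passed, and 0 over all genes. These lists were called whichever array was left out, but their medians moved. They ran from 0.24 to 0.66 for the regulatory, 0.25 to 0.61 for the plasmablast, 0.21 to 0.65 for the B-1 and 0.14 to 0.48 for the costimulation list. The cholesterol list was lower (20 of 24 negative, median -0.41, adjusted p = 4.10e-04; adjusted p = 0.346 with an estimated correlation), with 0 members passing either way, and was not called without IL-10+ control array 1 (adjusted p = 0.0695). Within slide 1 the same 5 lists were called, with medians of 0.66, 0.61, 0.65, 0.48 and -0.50, and slide as a block also called all 5.

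In HDM mice, several genes were called higher in IL-10+ cells, some of them on probes not well above background on the IL-10- arrays. Jchain was not well above background on any IL-10- HDM array and at least 84.9-fold higher (log2 fold change 7.23, SE 0.88, adjusted p = 0.014). Ccl22, well above background on all 6 arrays, was 32.9-fold higher (log2 fold change 5.04, SE 0.58, adjusted p = 0.013). The Ikaros family factors Ikzf1 (log2 fold change 5.85, SE 0.60, adjusted p = 0.0092) and Ikzf4 (at least 13.7-fold, adjusted p = 0.0092) were higher on the probes used, but other probes gave 1.56 and 2.01 for Ikzf1 (unadjusted p = 0.38 and 0.11) and 1.75 for Ikzf4. Tsen54, a subunit of the tRNA splicing endonuclease, was at least 32.3-fold higher (adjusted p = 0.0028), while its other probe gave -0.67 (unadjusted p = 0.30). Il10 was 392-fold higher (log2 fold change 8.61, SE 1.18, adjusted p = 0.026), or 6.83 on the log2 scale without IL-10- HDM array 3. Cd9 was 18.9-fold higher (log2 fold change 4.24, SE 0.80, adjusted p = 0.083). The endosomal protein Micall1 (at least 18.5-fold), the anchoring protein Akap1 (log2 fold change 5.29, SE 0.53), Gin1 (at least 10.5-fold), Csf2rb2 (at least 9.34-fold), the histamine receptor Hrh2 (at least 7.29-fold) and the phosphatase Cdc25c (at least 6.44-fold) were also called. Lgr4 was the 1 gene called in both control and HDM mice.

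In total 42 genes were called in HDM mice, 41 higher and 1 lower, with 3315 at an unadjusted p under 0.05. Every IL-10+ HDM array lay on slide 1 and every IL-10- HDM array on slide 2, so only the control arrays bridged the slides. With slide as a block 0 genes were called by limma and 2017 had an unadjusted p under 0.05. The sign of all 42 was kept, with all 42 at an unadjusted p under 0.05, and the median of the called genes going from 4.42 (median SE 0.570) to 4.03 (median SE 0.993). In that fit Il10 was at 7.67 (SE 2.21, adjusted p = 0.45), Ikzf1 at 6.49, Ikzf4 at 7.10, Jchain at 7.52, Akap1 at 5.33, Micall1 at 5.25, Hrh2 at 4.58, Csf2rb2 at 3.49, Cdc25c at 3.13 and Tsen54 at 4.18 (SE 0.63, adjusted p = 0.17). Gin1 fell from 4.89 (SE 0.67) to 2.19 (SE 0.67, adjusted p = 0.474), under its bound of 10.5-fold. Tsen54, at 4.18, also lay under its bound given above. Both bounds thus hold only without the slide term. Blocking on the replicate number also left 0 calls by limma, with 3716 genes and all 42 at an unadjusted p under 0.05. The count was 211, 112 and 12 without IL-10- HDM array 1, 2 or 3, was 22, 13 and 5 without IL-10+ HDM array 1, 2 or 3, and was 74 and 23 without IL-10+ control array 2 or 3. Tsen54 and Akap1 were called whichever array was left out. Without IL-10+ HDM array 3, Ikzf1 and Ikzf4 (adjusted p = 0.0507), Ccl22 (0.0571), Csf2rb2 (0.0571), Micall1 (0.0753), Jchain (0.0789), Hrh2 (0.0789), Cdc25c (0.0919), Il10 (0.0919) and Gin1 (0.106) were not called. Without IL-10+ HDM array 2, Ccl22 (0.0680), Jchain and Micall1 (0.0713), Gin1 (0.0960), Hrh2 (0.113) and Il10 (0.122) were not called. Without IL-10- HDM array 3, Ccl22, Csf2rb2 and Micall1 (0.0592), Cdc25c (0.0950), Hrh2 (0.0980) and Gin1 (0.0992) were not called. Without IL-10+ HDM array 1, Gin1 (0.0955), Cdc25c and Il10 (0.101) were not called, and without IL-10+ control array 3, Il10, Gin1, Cdc25c and Hrh2 (0.0555) were not called.

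The median of all genes in this comparison was 0.16, and it moved to -0.17 with arrays centred on the tested-gene median and to -0.64 with the deposited table, so list medians are given relative to it. Cholesterol (-1.16, 20 of 24 negative, adjusted p = 1.79e-07), heat shock (-1.15, 12 of 16, adjusted p = 5.79e-04), immediate early (-1.10, 15 of 21, adjusted p = 1.44e-04) and ribosomal protein genes (-0.90, 35 of 37, adjusted p = 2.54e-09) were lower in IL-10+ cells whichever array was left out. Before subtraction, leaving out 1 array gave medians of -0.95 to -0.40 for the ribosomal and -1.21 to -0.59 for the heat shock list. Both were smallest in size without IL-10- HDM array 3. With an estimated correlation the 4 lists gave adjusted p = 0.227, adjusted p = 0.355, adjusted p = 0.227 and adjusted p = 0.355. Adjusted over the list alone, 6 cholesterol and 2 immediate early genes passed, and 0 over all genes. The DNA replication (-0.84, adjusted p = 0.032), unfolded protein response (-0.75, 0.0090), oxidative phosphorylation (-0.63, 0.0090), protein translocation (-0.59, 0.032) and glycolysis (-0.53, 0.035) lists were also lower. The B-1 (0.60, 0.032), plasmablast (0.26, 0.036) and platelet (0.80, 0.045) lists were higher; the platelet list holds Cd9. The regulatory list was not called in HDM mice (adjusted p = 0.0515; 0.240 with slide as a block). With an estimated correlation none of these 8 was called, with adjusted p = 0.227 to adjusted p = 0.528. Adjusted over the list alone 5 B-1 members were higher and 1 lower, 4 plasmablast members and 1 platelet member were higher, and 1 unfolded protein response gene was lower; 1 B-1 and 1 plasmablast gene passed over all genes. With the deposited table the plasmablast and B-1 medians were -0.37 and -0.04 before subtraction. Both lay above the median of all genes there (-0.64), so they moved with the scale of all genes. Each of these 8 lists lost its call without at least 1 array: without IL-10- HDM array 1 all 8 did (adjusted p = 0.0671 to 0.287). Without IL-10- HDM array 2 the plasmablast (0.162), glycolysis (0.0711) and platelet (0.133) lists did, and without IL-10- HDM array 3 the DNA replication (0.158) and glycolysis (0.113) lists. Without IL-10+ HDM array 1 the platelet list (0.0569) did. Without IL-10+ HDM array 2 the DNA replication (0.0896), glycolysis (0.0923) and oxidative phosphorylation (0.0703) lists did, and without array 3 the plasmablast (0.101), translocation (0.0633), glycolysis (0.101) and platelet (0.0759) lists. In the fit with slide as a block, the 9 lower lists and the plasmablast (adjusted p = 0.044) and platelet (0.0199) lists were called, and the B-1 list (0.0530) was not.

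Between HDM and control mice, IL-10+ B cells differed in 1 called gene. The transcript ENSMUST00000100326 was at least 7.57-fold lower in HDM mice (log2 fold change -4.82, SE 0.35, adjusted p = 0.0016) and was not well above background on any IL-10+ HDM array. As it has no gene symbol, the 5 genes with the smallest p are given: the others were the carrier Slc16a13 (-3.75, SE 0.48), Epb41l1 (-2.67, SE 0.34; 0.96 on the probe used without a filter on dim probes) and 1700016C15Rik (3.00, SE 0.39), each with an adjusted p = 0.088, and an unannotated chromosome 5 transcript (-4.14, SE 0.57, adjusted p = 0.12). Il10 (-0.39, SE 1.18) and Cd9 (-0.57, SE 0.80) differed by less than their SE. There were 569 genes at an unadjusted p under 0.05, fewer than the share of 0.05 expected without any change. The count of called genes was 2 without IL-10- control array 1. All 6 arrays lay on slide 1, and the fit within that slide also called this 1 gene. The regulatory (median -0.24, adjusted p = 0.022), immediate early (-0.21, 0.019), protein translocation (-0.30, 0.0063) and oxidative phosphorylation (-0.13, 0.022) lists were lower in HDM mice. With an estimated correlation they gave adjusted p = 0.367 for the regulatory list and adjusted p = 0.718 for the others. No member passed over all genes or adjusted over the list alone. Without IL-10+ control array 2, each had an adjusted p = 0.812, and the shift of the protein translocation (-0.01) and oxidative phosphorylation (0.01) lists was gone. The immediate early and oxidative phosphorylation lists were also not called without IL-10+ control array 3 (0.126 each) or IL-10+ HDM array 2 (0.166 and 0.494), nor the regulatory list without IL-10+ HDM array 1 (0.101) or 3 (0.0667).

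In IL-10- B cells, the called genes were mostly lower in HDM mice. Tsen54 was at least 45.6-fold lower (log2 fold change -5.72, SE 0.40, adjusted p = 0.0012), while its other probe gave 0.27. Ikzf1 fell by 5.21 on the log2 scale (SE 0.60, adjusted p = 0.019), with -0.87 and -0.79 on its other probes, and Ikzf4 was at least 10.4-fold lower (adjusted p = 0.019), with -1.57 on its other probe. Ccdc32 (at least 28.2-fold), the laminin chain Lamc1 (at least 10.3-fold), the leukotriene receptor Ltb4r2 (at least 3.74-fold) and the Myc partner Max (at least 3.04-fold) were lower, as was Akap1 (log2 fold change -4.59, SE 0.53). Fars2, a mitochondrial tRNA synthetase, was at least 5.88-fold higher (adjusted p = 0.041). Il10 (-2.45, SE 1.18, adjusted p = 0.56; -0.66 without IL-10- HDM array 3) and Cd9 (-0.01, SE 0.80) did not pass. Tsen54, Ikzf1, Ikzf4 and Akap1 were also called between IL-10+ and IL-10- cells of HDM mice, a comparison that uses the same 3 IL-10- HDM arrays.

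This comparison called 12 genes, 1 higher and 11 lower, with 2274 at an unadjusted p under 0.05. The count was 26 without IL-10+ control array 2, was 6, 3 and 4 without IL-10- control array 1, 2 or 3, and was 128, 53 and 4 without IL-10- HDM array 1, 2 or 3. Tsen54 was called whichever array was left out. Without IL-10- control array 3 none of the other named genes was called (adjusted p = 0.0775 to 0.117). Without IL-10- control array 2 Ikzf4 remained, and the others had an adjusted p of 0.0552 to 0.137; without IL-10- HDM array 3 Ikzf1 remained, and the others had 0.0604 to 0.114. Without IL-10- control array 1, Ikzf1, Ikzf4, Lamc1 (each 0.102), Max (0.105), Ltb4r2 (0.0637) and Fars2 (0.143) were not called. Leaving out arrays of the IL-10+ groups ended calls of Fars2, Lamc1 and Ltb4r2, with an adjusted p up to 0.0968 without IL-10+ control array 1, and Lamc1 was not called without IL-10- HDM array 2 (0.0565). With slide as a block 0 genes were called by limma, with 1704 at an unadjusted p under 0.05, and all 12 kept their sign, with a median of 4.82 (median SE 0.762) against 4.90 (0.541). In that fit Tsen54 was at -5.02 (adjusted p = 0.063), Ikzf1 at -5.64, Ikzf4 at -6.13, Ccdc32 at -5.37, Lamc1 at -4.54, Akap1 at -4.62, Ltb4r2 at -3.98, Max at -3.61 and Fars2 at 5.23. The value of Tsen54 was smaller in size than its bound given above, so that bound holds only without the slide term. Within slide 2, which held 1 control array that was assumed to vary like the HDM arrays, 0 genes were called by limma and 986 had an unadjusted p under 0.05. The ribosomal protein (median 0.68, 35 of 37 positive, adjusted p = 1.11e-09), unfolded protein response (0.65, 20 of 28, 0.0088), heat shock (0.60, 16 of 16, 0.0056) and cholesterol (0.55, 20 of 24, 0.030) lists were higher in HDM mice. With an estimated correlation each had adjusted p = 0.662, and 0 members passed over all genes or adjusted over the list alone. In the fit with slide as a block, camera called these 4 lists and also the protein translocation (0.54, adjusted p = 0.00659), glycolysis (0.66, 0.0146) and oxidative phosphorylation (0.67, 0.00573) lists higher and the platelet list lower (-1.07, 0.0331). The median of all genes was -0.04 here and 0.60 with the deposited table. The ribosomal list was called whichever array was left out, the heat shock list not without IL-10- HDM array 3 (0.159), the unfolded protein response list not without IL-10- control array 3 (0.347) or IL-10- HDM array 1 (0.124), and the cholesterol list not without IL-10- control array 3 (0.347) or IL-10- HDM array 1 (0.0598) or 3 (0.185). Without IL-10- HDM array 3 the ribosomal and heat shock medians were 0.36 and 0.29.

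The IL-10 contrast differed between HDM and control mice for 3 genes, tested as an interaction. Tsen54 had a log2 fold change of -0.63 in control and 5.23 in HDM mice (difference 5.86, SE 0.56, adjusted p = 0.025), and its other probe gave a difference of -0.48 (unadjusted p = 0.59). Gspt2, a translation termination factor, had -3.39 in control and 3.21 in HDM mice (difference 6.60, SE 0.77, adjusted p = 0.047). ENSMUST00000100326 had 4.47 in control and -0.14 in HDM mice (difference -4.62, SE 0.49, adjusted p = 0.031). Il10 (2.05, SE 1.67, adjusted p = 0.79; 0.26 without IL-10- HDM array 3) and Cd9 (-0.56, SE 1.13, adjusted p = 0.91) gave no detectable difference. Of all genes, 1610 had an unadjusted p under 0.05. The count was 0 without any 1 of the 3 IL-10+ control arrays, IL-10+ HDM array 1 or 2, IL-10- control array 1 or 2, or IL-10- HDM array 3, was 1 without IL-10+ HDM array 3 and was 14 without IL-10- HDM array 1. Gspt2 kept its call in 1, ENSMUST00000100326 in 2 and Tsen54 in 3 of the 12 omissions, with an adjusted p up to 0.191, 0.141 and 0.135. With slide as a block 0 genes were called by limma, 1687 had an unadjusted p under 0.05, and the 3 differences were 5.16, 6.88 and -4.49, each with an adjusted p = 0.170. Relative to the median of all genes (0.16), the IL-10 contrast was lower in HDM mice for the unfolded protein response (-0.96, adjusted p = 0.0043), glycolysis (-0.94, 0.011), ribosomal (-0.93, 6.59e-08), heat shock (-0.82, 0.012), immediate early (-0.80, 0.012), cholesterol (-0.78, 0.014), oxidative phosphorylation (-0.75, 0.0097) and protein translocation (-0.68, 0.0074) lists. With an estimated correlation they gave adjusted p = 0.547 or adjusted p = 0.575. With quantile normalisation 0 of the 8 were called. In the fit with slide as a block, camera called the same 8 lists and also the DNA replication list lower (-0.65, adjusted p = 0.0458) and the platelet list higher (1.23, 0.0458). The ribosomal list was called whichever array was left out; the other 7 were not called without IL-10+ control array 2 (adjusted p = 0.0722 to 0.143) or IL-10- control array 3 (0.0683 to 0.106). Without IL-10- control array 1 the protein translocation (0.0534), heat shock, immediate early and oxidative phosphorylation lists (0.0755 each) were not called, and without IL-10+ HDM array 2 the cholesterol, heat shock and oxidative phosphorylation lists (0.0678 each). Without IL-10- HDM array 3 the immediate early (0.0617), cholesterol (0.128) and heat shock (0.170) lists were not called, and without IL-10- HDM array 1 the translocation list (0.0754). The regulatory, plasmablast and B-1 lists were not called in this comparison, so their shift was not shown to differ between control and HDM mice.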

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

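The look at second probes and at detection was chosen only after these results were seen, and the test of the count was set beforehand. For 3 genes the difference between IL-10+ and IL-10- cells was itself different between HDM and control mice by the interaction test. Tsen54 differed by 5.86 on the log2 scale, and its probe was well above background on all arrays of 3 groups and on 0 of the 3 IL-10- HDM arrays; a second Tsen54 probe gave -0.48 (unadjusted p = 0.59). ENSMUST00000100326 differed by -4.62 and was well above background in IL-10+ control cells alone, on 3 of 3 arrays. Gspt2 differed by 6.60 and was well above background on all 3 IL-10- control and all 3 IL-10+ HDM arrays and on 0 of the other 6.

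All 3 patterns set groups with a measured signal against groups without one, so the sizes depend on how the dim arrays are scaled and are not folds between measured levels. In 1 of 100 random deals of the residuals of the model without the interaction, the real one included, as many as 3 genes were called, and the highest other count was 1. A count of 3 was thus rare among the deals. They treat all arrays as alike, though the array weights ran from 0.187 to 2.60, and they take no account of slide. For so small a count they therefore exclude neither chance nor slide. With slide as a block the differences were 5.16, -4.49 and 6.88 with an adjusted p of 0.170 each, and their SE rose (median 0.564 to 0.630). No biological explanation was tested for these genes, and a difference between HDM and control mice stays open.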

How the results depend on the processing

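Leaving out IL-10- HDM array 3 and IL-10+ control array 2 together was chosen only after the data were seen; the other alternatives were planned. The 6 gene counts were 4, 42 and 67 for IL-10+ against IL-10- cells in control mice, in HDM mice and averaged, 1 and 12 for HDM against control mice in IL-10+ and in IL-10- cells, and 3 for the interaction, with 10 lists called in the averaged comparison. Where an alternative gave a count of 0, limma gave 281 to 3716 genes at an unadjusted p under 0.05. A share of 0.05 of the tested genes is expected there without any change, so these counts alone show no remaining difference. Unless a cause is given, the cause was not tested.

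The log2 difference of Il10 in IL-10+ versus IL-10- B cells averaged over both mice stayed positive in every alternative, at 6.59 to 7.63 where no single array was left out. Its exact permutation p, taken without blocks, was at most 0.01. In limma it lost its call with slide as a fixed block (6.96, adjusted p = 0.266) and with the replicate block (7.59, adjusted p = 0.0811). It has no value when probes must be well above background on all 12 arrays, because IL-10- HDM array 3 fails that filter.

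Quantile normalisation called 7 genes in control mice, 3 between HDM and control mice in IL-10+ cells and 0 in the interaction. Normexp background correction called 10 in control mice, 24 in HDM mice, and 0, 4 and 0 in the last 3 comparisons; with quantile normalisation added it called 12 in control mice and 0, 4 and 0. Normexp shared 2 of the 4, 14 of the 42 and 37 of the 67 sort calls (63 called averaged), so many of these calls depend on the background correction. Centring on the tested-gene median called 2 in control mice, 20 in HDM mice and 6 in IL-10- cells. The deposited table called 2, 7 and 26 for the sort, 6 in IL-10- cells and 0 in the interaction, and 25 of its 26 averaged calls were among the 67. With it the median of all genes moved from 0.07 to -0.21 in IL-10+ cells, from 0.04 to -0.29 in the averaged comparison and from 0.16 to -0.78 in the interaction.

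No filter on dim probes called 2 genes in control mice, and a filter at 6 arrays called 1 in control mice, 0 in IL-10+ cells and 1 in the interaction. The filter at all 12 arrays called 1, 6 and 30 for the sort, 0, 0 and 0 in the other comparisons, and 4 lists; this filter tests fewer genes, and 21 of the 30 were among the 67. It also moved Tsen54 to its other probe, which reversed it to -0.67 in HDM mice, 0.27 in IL-10- cells and -0.48 in the interaction, and it took the B-1 list in HDM mice to -0.0383. The mean of a gene's probes called 0 in the interaction. Without a filter Epb41l1, through another probe, was at 0.96 instead of -2.67 in IL-10+ cells.

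Fitting only the groups compared called 0 in control mice and 0 in IL-10- cells. The trend and robust options called 0 in control mice, 0 in IL-10+ cells, 7 in IL-10- cells and 0 in the interaction. Array weights, which gave IL-10- HDM array 3 a weight of 0.187, called 12 in control mice, 128 averaged and 6 in IL-10+ cells. Slide as a fixed block called 0 in HDM mice, averaged, in IL-10- cells and in the interaction. For the averaged calls this came with a median SE of 0.732 instead of 0.438 at a median of 3.22 instead of 3.27. Slide as a random block (consensus correlation -0.05) called 105 in HDM mice and 123 averaged, and within slide 2 there were 0 calls in IL-10- cells. The replicate number as a block called 0 for each of the 3 sort comparisons and the interaction, and 3 in IL-10- cells. For the sort the folds were the same and the averaged calls had a median SE of 0.401, so the calls ended with the fall from 8 to 4 residual degrees of freedom. The residuals of arrays with the same number correlated by 0.019 to 0.149, over 0.1 for 2 of 6 pairs, and the same number gave the highest correlation in 6 of 6. Pairing is thus not excluded, though the labels do not state it. The main fits and the permutation test were unpaired, so their p-values ignore a pairing if there was one. The estimated correlation called 3 lists. Without IL-10- HDM array 3 and IL-10+ control array 2 together, 21 genes were called in HDM mice, 39 averaged and 0 in the interaction.

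Cd9 in HDM versus control mice in IL-10- B cells was at -0.01 (SE 0.80), and its sign changed within that SE: 0.63 with quantile normalisation, 0.0818 with normexp, 0.21 with both, 0.28 with the tested-gene median, 0.73 with array weights, 0.00721 with slide as a random block, 0.64 with the deposited table and 0.75 without the pair of arrays. Leaving out IL-10- control array 2 or 3 or IL-10- HDM array 3 gave 0.56, 0.10 and 0.75, over a range of -0.69 to 0.75 for all 12 omissions. The interaction for Cd9 was 0.12 without IL-10- control array 1, over a range of -1.31 to 0.12. These values were not called.

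Leaving out 1 array at a time gave 1 to 7 genes in control mice, 5 to 211 in HDM mice and 31 to 137 averaged. It gave 1 to 2 in IL-10+ cells, 3 to 128 in IL-10- cells, 0 to 14 in the interaction, 8 to 10 lists, and 6.69 to 8.04 for Il10. Across the other alternatives, named genes kept direction and side of the threshold in 621 cases, lost the call in 284, gained it in 16 and reversed in 12. Called lists kept theirs in 580, lost the call in 188 and reversed in 1. Signal over background limits most folds, since many of the called genes were not well above background on the dim side.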

Other observations

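The tests of faint transcripts, of immunoglobulin segments, of the single array and of the region around Il10 were chosen only after the results they concern were seen; the tests of array 3, of slide and of other splits were set beforehand.

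Immunoglobulin segments moved with the sort as a family. Of 129 segments, 123 were higher in IL-10+ cells in the averaged comparison, with a median log2 fold change of 1.74 (camera p = 7.65e-40; p = 0.00115 with an estimated correlation) and 6 called, and 115 to 126 were higher under each scaling. The median was 1.43 in control and 1.97 in HDM mice, and 1.86 with slide as a block. By contrast 24 T cell receptor segments had a median of -0.08, with 11 positive. Segments share sequence, so their probes are not independent. Among constant regions in the averaged comparison, none of the 7 measured was called: kappa was at 1.35 (SE 0.29, adjusted p = 0.115), gamma 1 at 1.97 (SE 0.62, adjusted p = 0.341), lambda 2 at 0.95 (adjusted p = 0.386) and mu at 0.58 (SE 0.23, adjusted p = 0.474). Gamma 3 (2.56, SE 1.62), gamma 2C (0.19, SE 1.08) and epsilon (-0.10, SE 0.61) lay within 2 SE of 0.

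IL-10- HDM array 3 stood apart from the other 11 arrays. Of 11244 genes well above background on those 11 and at least 4 log2 units above the floor, 875 (7.78%, 95% exact interval 7.29% to 8.29%) were not well above background on it, against at most 0.388% on any other array. A dimmer hybridisation or scan would take genes near the floor first and leave such genes, so the 875 lost genes argue against it. The loss was 13.0% in the fainter and 2.54% in the brighter part of these genes, which is consistent with loss of transcripts during amplification of little RNA. Cells of another type could not be excluded. The highest median difference from the other IL-10- HDM arrays among 8 marker lists was 0.12 (erythroid). The most abundant markers Itgam (8.94 against 8.55) and Csf3r (7.64 against 7.44) moved little. Fainter ones such as Gp6 (0.40 against -2.87) and Il1r2 (1.76 against -0.65) were higher, Pecam1 (1.33 against 2.34) was lower, and the members went both ways.

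More genes were higher than lower in IL-10+ cells in the averaged comparison, 61 of 67 (91.0%). Immunoglobulin segments that move as one were 6 of the 67, too few to make the excess, which without them was 55 of 61 (90.2%). Loss of faint transcripts on IL-10- arrays stays open. Of the called genes well above background on all 12 arrays 81.0% (17 of 21) were higher, but that set leaves out the genes that are dim on one side, so it decides nothing about them. The biology of the sorted cells, which the design names, stays open and was not tested.

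The 41 genes called higher in IL-10+ cells of HDM mice had a median of 4.44 there, where sort and slide coincide. Slide as the whole cause is argued against by the control arrays of slide 1 alone, where the same genes had a median of 1.27, with 31 of 41 positive. The central 95% of 10000 random gene sets reached up to 0.257 there. Those sets were matched on level alone and drawn gene by gene. They take no account of genes that move together, so their range may be too narrow. Without the single array IL-10- HDM 3 the median of the 41 genes was 4.34, with 12 of them still called, so the size of their median did not rest on that array alone. Genes low on that array alone would have a large spread and seldom be called. The median could therefore hardly have fallen, and it does not exclude an effect of that array on the calls. As the value in control mice was smaller, a share of slide, of HDM allergy or of the choice of genes for their size in HDM mice may remain in the 4.44, and from the HDM arrays alone slide and sort cannot be told apart.

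Il19 lies beside Il10 on chromosome 1, and both were higher in IL-10+ cells. If transcription were raised across the region, its other neighbours should rise too. The 9 other genes among the 5 nearest tested on each side had a median of 0.28 (SD 1.20) with 6 positive, below the bound of Il19 (at least 30.1-fold) and its other probe (2.68), and 18.2% of 15480 windows of 9 genes had one at least as large. Il20 (0.01, SE 0.45) and Il24 (0.28, SE 0.30) beside them moved little, while Ikbke (3.01, SE 0.96) and Fcmr (1.96, SE 0.56) were higher but not called. This argues against a rise of the size of the Il19 bound across the whole region. Against the other Il19 probe it is weaker, as Ikbke lay above that value. Regulation of Il19 and Il10 themselves is left as an untested possibility.

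Other splits of the arrays were counted for each gene count. For the averaged comparison, 1 of 100 splits within control and within HDM mice, the real one, gave as many as 67 genes. The highest other gave 31 (with IL-10+ control array 2 and IL-10- control array 3 exchanged), so a count of 67 was rare among the splits. They treat the arrays as alike, though the array weights ran from 0.187 to 2.60, and ignore a pairing if there was one. Chance is thus excluded at that share only if the arrays can be exchanged. These splits take no account of slide, and the 4 arrays of slide 2 were all IL-10-, so they say nothing against slide. With slide as a block limma called 0 genes (1757 at an unadjusted p under 0.05), at a median of 3.22 instead of 3.27 and a median SE of 0.732 instead of 0.438. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For the sort in control mice 2 of the 10 gave at least the real 4 (highest other 5), and in HDM mice 1 gave the real 42 (highest other 1). Between HDM and control mice, 6 gave at least the real 1 in IL-10+ cells (highest other 3). In IL-10- cells 1 gave the real 12, and the highest other gave 11. That other split set IL-10- control arrays 1 and 2, the only ones on slide 1, and IL-10- HDM array 1 against the rest, so it follows the slides in part. With slide as a block limma called 0 genes (1704 at an unadjusted p under 0.05), but the median of the 12 was 4.82 instead of 4.90 and the median SE rose from 0.541 to 0.762, so the lost calls do not show slide to be the cause. The fit within slide 2 rests on 1 control array.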
